A study of Mus musculus with 28 samples.

How the data were processed

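Total RNA of dorsal skin was hybridised to 28 Illumina BeadChip arrays after biotin labelling, per the labels' protocols. Samples were grouped by age and genotype as the labels give them, and slide and position on the slide were taken from the sample descriptions. The deposited table of raw values holds, per the file headers, a bead signal and a detection p-value for each of 25697 probes on each array. The signals are intensity values on a linear scale that the authors deposited before any normalization, judged from array medians between 53.2 and 172, and the detection p-value measures each signal against negative control beads. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. A second deposited table holds the authors' processed intensity values of the same arrays. Nothing in the sources used here states how these were made. Set against the raw signals, each column kept the rank order of its own array, 25.6% of values were below 0, and column medians lay between 26.5 and 27.2, so the values are linear, background-subtracted and alike in distribution. They were used only as an alternative, on a log2 scale after values below 16 were set to 16, which held for 43.9% of them.

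Raw signals were background-corrected with the normexp method from the detection p-values (limma neqc, offset 16), quantile-normalized and put on a log2 scale. A probe was tested where its detection p-value was below 0.01 on at least 6 arrays, which left 12834 probes. Gene symbols came from the platform annotation, in which 23978 probes have 1 symbol, 0 have several and 1719 have none. Symbols were checked through the gene ID in a RefSeq gene table of the assembly GRCm38.p6, used for names only, for 23962 probes. No genome build is named for the data, so no coordinates are printed. Of the tested probes 732 had no symbol and were left out of the gene tests. For the 2257 genes with more than 1 tested probe, the probe with the highest mean signal stood for the gene, which gave 9045 genes. Probes of 1 gene could disagree: another probe passed the threshold in the opposite direction for 6 called genes at P10, 5 at P15, 1 for the difference and 6 for age, and none of these is named for that contrast.

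Each probe was fitted with lmFit and eBayes (limma 3.58.1 in R 4.3.3) with 4 groups and 4 slides as terms, all 28 arrays sharing 1 estimate of the spread (21 residual degrees of freedom). A gene passed where its Benjamini-Hochberg adjusted p was below 0.05. With the slide term the P10 effect rests on slides 1 and 2, and the P15 effect and the age change on slides 3 and 4. The SE of a fold is on the log2 scale, and means and SDs are of normalized log2 signals. Adjusted p-values without another name are from these limma fits for genes and from the list test described below (camera) for gene lists. Of the genes past the threshold, those with the 8 largest rises and 8 largest falls at P10 and P15, and the 5 largest for the other contrasts, were named where every sample of the first group lay on the called side of its slide's reference mean. Accession-like, Rik, LOC and Gm names were left out. Gab1 was always named, and from each list up to 4 members with the smallest p. Shared genes named beside the overlap were chosen after their values were seen. The groups, lists, gene and list tests and naming rule were fixed before the data were examined, unlike the muscle and brightness covariates, the younger-profile tests and the folds of probes detected on some arrays only.

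The 34 gene lists covered follicle layers, epidermis, glands, fat, dermis, muscle, blood and immune cells, nerve and signalling pathways. They were tested with camera at its preset correlation of 0.01, two-sided, adjusted over 136 tests, with camera at an estimated correlation beside it. At the estimated correlation, calls held for keratin-associated proteins, hair shaft keratins and cell proliferation at P15 and for adipocyte, cell proliferation and hair shaft keratin lists in the difference. Slides of a pair have the same layout, so arrays at the same position were checked as possible repeat hybridisations. Their deviations correlated between -0.35 and 0.20, under the required 0.5, and all arrays were kept as separate samples. Repeat hybridisations within a slide were not checked. In each group the closest pair of arrays lay on the same slide. Signals correlated at 0.995 for P10 mutants 1 and 2 (group median 0.986) and at 0.990 for P10 controls 5 and 6 (group median 0.964), all on slide 1. Whether replicate numbers pair samples was checked by residuals of the fit with group and slide terms, which correlated between -0.20 and 0.41. P10 number 5 (0.41) and P15 numbers 3 (0.14) and 4 (0.16) exceeded the 0.1 needed. The other numbers did not, and the numbers were not taken as pairs. The gene fits were tested on simulated data with 200 changed genes among 9045. For the P10 comparison they recovered 97.0% of 2-fold and 55.0% of 1.5-fold changes with 9 false calls, and for P15 they recovered 91.0% and 51.0% with 7 false calls. The simulated noise was independent between genes and held no outlying array, so these figures need not hold for the real arrays. Alternatives covered background correction, scaling, the authors' processed values, the filter, the slide term, array weights, probes per gene, a fold threshold, Xist signal as a covariate, blocks, single slides and leaving out each array.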

Results

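Gene expression was measured in mouse dorsal skin on Illumina BeadChip arrays, on which each probe's signal is the mean brightness of many identical beads. Skin of control mice was set against skin of mice that carried a conditional Gab1 allele and the K14-cre transgene, which is active in the basal keratinocytes of epidermis and hair follicle. Gab1 is an adaptor protein that links receptor tyrosine kinases to the Ras and ERK cascade. The 28 arrays comprised 10 P10 controls, 6 P10 mutants, 6 P15 controls and 6 P15 mutants, from animals 10 and 15 days old on a mixed genetic background. They lay on 4 slides. P10 mutants shared slides 1 and 2 with 6 P10 controls, and the P15 arrays shared slides 3 and 4 with the other 4 P10 controls. The number of probes detected above background ranged from 8836 to 13610 per array, and the median raw signal from 53.2 to 172. The extremes at 8836 and 172 belonged to 1 array, P15 mutant replicate 5, on slide 3. The number of arrays limits the precision. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples. Mutant-control differences were taken within slides, so the P10 and P15 effects rest on different arrays. On every slide mutants lay at positions A to C and the controls of their age at D to F. P10 controls on slides 3 and 4 lay at G and H. Genotype and position on the slide therefore cannot be told apart.

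Gab1 itself was examined first, since it checks the labels. Its probe (ILMN_1222009) gave a normalized log2 signal of 11.30 ± 0.24 (SD, n = 6) in the P10 controls of slides 1 and 2 and 9.99 ± 0.12 (SD, n = 6) in P10 mutants. The 10 P10 controls together had a mean of 11.33 ± 0.24. At P15 the values were 11.60 ± 0.20 (SD, n = 6) in controls and 10.28 ± 0.23 (SD, n = 6) in mutants. Gab1 was therefore 2.47-fold lower in P10 mutants (SE 0.11 on the log2 scale, limma adjusted p = 1.48e-08) and 2.51-fold lower in P15 mutants (SE 0.11, limma adjusted p = 2.20e-09), in 6 of 6 mutants each time. The effects at the 2 ages differed by -0.02 on the log2 scale (limma adjusted p = 0.966). The exons that the allele deletes are not given in the sources used here, and skin also holds cells in which K14-cre is not active.

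**Figure D1:**
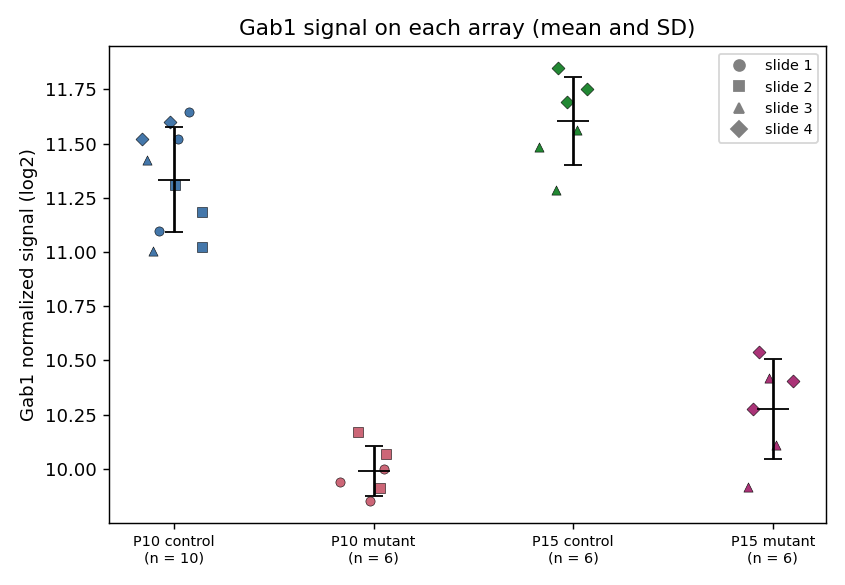
Normalized log2 signal of the Gab1 probe on each of the 28 arrays, by group, with marker shape for the slide, the horizontal bar for the group mean and the whisker for the SD. Every mutant array lies below every control array, with P10 mutants between 9.85 and 10.17 and P15 controls between 11.29 and 11.85.

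The first comparison asked which genes differed between mutant and control skin at P10. Mutant skin had lower signals of Lce3c, Lce3b, Upk1b and 3 lists of follicle genes and higher signals of genes of muscle, dermis and fat, but these list calls ended with an estimated correlation (adjusted p from 0.0512 to 0.417). Of 9045 genes tested, 1687 passed the threshold, 849 of them higher and 838 lower, and 133 of the higher and 78 of the lower ones changed at least 2-fold. Lce3c and Lce3b, late cornified envelope genes, were 6.03-fold (SE 0.49 on the log2 scale, limma adjusted p = 0.00044) and 2.99-fold (SE 0.47, limma adjusted p = 0.00976) lower. The call of Lce3b, detected on 4 of 6 mutants, ended on slide 1 alone and with the muscle list score as a covariate. Upk1b, a uroplakin of barrier epithelia, was detected in 6 of 6 controls and 0 of 6 mutants and was at least 3.10-fold lower (limma adjusted p = 2.32e-10). Here and below, "at least" marks a group in which the probe was detected on no array: that group was set, array by array, at the higher of its own value and the lowest signal of any detected probe. Where a probe was detected on some arrays of a group only, the fold was taken with its arrays set in the same way, while SE, p and the order of genes are those of the fitted differences. Fxyd4, a regulator of the sodium pump, fell 4.37-fold (SE 0.25), and the isopentenyl diphosphate isomerase gene Idi2 fell 4.42-fold (SE 0.32). The nicotinic receptor subunit Chrna4 fell 3.43-fold, the transporter gene Slc23a3 3.49-fold and the histone variant gene H2al1e 3.56-fold. The 8 largest rises were led by 7 genes of striated muscle, namely Myh4 (3.41-fold), Sln (4.22-fold), Ppp1r27 (3.53-fold), Ckm (3.89-fold), Csrp3 (3.84-fold), Cox6a2 (3.79-fold) and Tnnt3 (3.78-fold), with adjusted p from limma between 0.00646 and 0.0351 and SEs between 0.50 and 0.69. The calls of Sln, Ckm, Cox6a2 and Tnnt3 ended with the authors' processed values. Those of Myh4, Ppp1r27 and Ckm ended on slide 1 alone. Those of Sln, Ppp1r27, Csrp3 and Cox6a2 ended with the muscle list score as a covariate. Those of Sln, Ckm and Cox6a2 also ended without any of P10 controls 5, 6, 8 and 9 and P10 mutants 1, 2, 4 and 6 (adjusted p from 0.0501 to 0.112). Those of Csrp3 and Tnnt3 ended without any of P10 controls 5 and 6 and P10 mutants 1, 2 and 6 (adjusted p from 0.0553 to 0.0958). The call of Csrp3 also ended without P10 control replicate 9 (adjusted p = 0.0508). The remaining one was Mup2, a major urinary protein gene (3.62-fold, SE 0.45, limma adjusted p = 0.00559). As the rule for naming genes required, 6 of 6 mutants lay on the called side of the control mean of their slide.

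Gene lists fixed before the data were examined described the P10 effect by tissue layer. Of 24 dermal extracellular matrix genes 18 rose and 0 fell (median log2 difference 0.62, camera adjusted p = 2.34e-10; adjusted p = 0.0512 with an estimated correlation), among them the collagen genes Col6a2 (1.93-fold, SE 0.13) and Col3a1 (3.43-fold, SE 0.28), Sparc (1.66-fold) and Pcolce (1.90-fold). The call of Sparc ended with median scaling and that of Pcolce on slide 2 alone. Of 16 adipocyte genes 12 rose and 0 fell (median 0.76, camera adjusted p = 1.51e-08; adjusted p = 0.147 with an estimated correlation), including the lipid droplet gene Plin4 (1.80-fold), the lipase gene Lipe (1.89-fold), the adipokine gene Adipoq (1.87-fold) and Nnat (log2 difference 1.04). Of 21 skeletal muscle genes 9 rose (median 1.55, camera adjusted p = 2.95e-06; adjusted p = 0.417 with an estimated correlation). Muscle values were widely spread among controls: on P10 control replicate 7 the mean centred score of this list was 2.23, above the 1.22 to 2.03 of the mutants, against -0.32 to 0.55 on the other 9 P10 controls. Of 7 mast cell genes 6 rose (median 0.78, camera adjusted p = 0.000185; adjusted p = 0.123 with an estimated correlation), including the protease genes Mcpt4 (1.97-fold) and Tpsab1 (1.62-fold). With the muscle score as a covariate the mast cell median was 0.45. The calls of Tpsab1 (adjusted p = 0.0512), Hdc and Cma1 then ended, while that of Mcpt4 held. Of 19 immune cell genes 7 rose and 2 fell (median 0.35, camera adjusted p = 0.0309; adjusted p = 0.361 with an estimated correlation). The 2 that fell encode T cell receptor complex chains, Cd3g (2.63-fold lower) and Cd3e (1.86-fold lower), while the macrophage gene Adgre1 rose 2.24-fold. The immune cell call ended under 9 of 36 alternatives, among them slide 2 alone (adjusted p = 0.0719) and the omission of P10 control replicate 6, P10 control replicate 10 or P10 mutant replicate 4 (adjusted p from 0.0515 to 0.0670). Of 28 epidermal differentiation genes, which include Lce3b and Lce3c, 2 rose and 3 fell at P10 (median 0.01, camera adjusted p = 0.908).

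Among the follicle lists, 3 had lower values in P10 mutants. There was no camera call for hair shaft keratins (2 of 10 higher, 0 lower, adjusted p = 0.936), hair matrix regulators (adjusted p = 0.463) or bulge stem cell genes (adjusted p = 0.391). Of 28 genes for keratin-associated proteins, which crosslink keratin filaments in the hair shaft, 13 fell and 3 rose (median -0.40, camera adjusted p = 0.000302; adjusted p = 0.270 with an estimated correlation), led by Krtap4-1 (2.80-fold lower, SE 0.18) and Krtap5-4 (2.48-fold lower, SE 0.16). Of 8 inner root sheath genes 4 fell (median -0.24, camera adjusted p = 0.00923; adjusted p = 0.0569 with an estimated correlation), with Tchhl1 1.90-fold and Krt72 1.70-fold lower. Of 10 outer root sheath and companion layer genes 4 fell, with Barx2 1.66-fold and Sox9 1.61-fold lower. The list median was -0.35 (camera adjusted p = 0.0437, and adjusted p = 0.201 with an estimated correlation). This call ended under 12 of 36 alternatives, among them the muscle score as a covariate (adjusted p = 0.169) and the omission of P10 control 8 or P10 mutant 4, 5 or 6 (adjusted p from 0.0555 to 0.171). With median scaling the inner root sheath median was -0.61. On slide 1 alone the calls of the 3 lists ended (adjusted p from 0.195 to 0.534). Adjusted over the list alone, the numbers changed little for the dermal matrix (19 higher), the adipocyte (12 higher) and the keratin-associated protein list (4 higher, 14 lower), while 19 of the 21 muscle genes passed. On slide 1 and on slide 2 taken alone, the medians were 0.65 and 0.65 for dermal matrix, 0.51 and 0.99 for adipocyte, 1.32 and 1.72 for muscle, 0.80 and 0.88 for mast cell, 0.37 and 0.27 for immune cell, -0.34 and -0.25 for keratin-associated protein, -0.35 and -0.24 for inner root sheath and -0.27 and -0.31 for outer root sheath genes.

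The P10 tests used limma with the slide as a term. Alone, slide 1 gave 3753 genes and slide 2 gave 848, weighting arrays by their quality gave 4301, and without P10 control replicate 6 the count was 1049.

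The second comparison asked the same at P15. The largest rises included Sprr2d, Krt42 and the beta-defensin genes Defb4 and Defb14, and the largest falls again included Upk1b, Chrna4 and Fxyd4. Of the 9045 genes 1774 passed, 862 higher and 912 lower, and 94 and 154 of them changed at least 2-fold. Sprr2d, a small proline-rich protein of the cornified envelope, was 9.73-fold higher in mutants (SE 0.34 on the log2 scale, limma adjusted p = 1.03e-09), although it was detected on only 1 of 6 controls. The keratin gene Krt42 rose 12.1-fold (SE 0.17, limma adjusted p = 5.76e-14). The antimicrobial beta-defensin genes Defb4 and Defb14 were detected on 0 of 6 controls and were at least 5.68-fold and at least 3.07-fold higher, and the neutrophil chemoattractant gene Cxcl1 was at least 2.45-fold higher (limma adjusted p = 3.16e-11). Lcn2, which encodes an iron-binding antimicrobial protein, rose 7.88-fold (SE 0.20), the chitinase-like gene Chil1 7.10-fold (SE 0.21) and Wfdc18 4.71-fold (SE 0.30). Upk1b was at least 3.16-fold lower (limma adjusted p = 8.28e-14), Chrna4 at least 3.69-fold, the kallikrein gene Klk15 at least 2.50-fold, the protease inhibitor gene Spink6 at least 1.98-fold and the lipocalin gene Lcn12 at least 1.91-fold. Dio3, which inactivates thyroid hormone, fell 4.91-fold (SE 0.17, limma adjusted p = 4.64e-12), the hepcidin gene Hamp2 7.02-fold (SE 0.28) and Fxyd4 4.71-fold (SE 0.25). As the rule for naming genes required, 6 of 6 mutants lay on the called side.

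By list, hair shaft genes were lower and proliferation genes higher in P15 mutants. Of the 28 keratin-associated protein genes 20 fell and 0 rose (median -0.66, camera adjusted p = 1.88e-16; adjusted p = 0.0163 with an estimated correlation), with Krtap31-2 4.18-fold and Krtap31-1 3.78-fold lower. Of 10 hair shaft keratins 6 fell (median -0.29, camera adjusted p = 0.000479; adjusted p = 0.0163 with an estimated correlation), including Krt87 (1.90-fold) and Krt40 (1.74-fold). Of 21 cell proliferation genes 14 rose and 0 fell (median 0.56, camera adjusted p = 3.09e-10; adjusted p = 0.0211 with an estimated correlation), such as the replication licensing gene Mcm2 (1.82-fold, SE 0.12), the mitotic regulator Cdc20 (1.73-fold) and Birc5 (1.68-fold). Of 13 melanocyte genes 10 rose and 1 fell (median 0.78, camera adjusted p = 7.29e-06; adjusted p = 0.148 with an estimated correlation), including the pigment synthesis genes Dct (2.16-fold, SE 0.15) and Oca2 (2.17-fold) and the melanosome gene Mlana (1.99-fold). Of 13 Wnt pathway targets 5 rose (median 0.38, camera adjusted p = 0.00446; adjusted p = 0.0984 with an estimated correlation), with Wnt10b 1.93-fold, the Wnt inhibitors Wif1 1.84-fold and Sfrp1 1.78-fold, and Apcdd1 1.44-fold higher. Of 19 epidermal stress response genes 8 rose and 2 fell (median 0.40, camera adjusted p = 0.000214; adjusted p = 0.200 with an estimated correlation).

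Lists of other tissue components gave smaller or less certain shifts at P15. Of 16 adipocyte genes 6 fell and 0 rose (median -0.43, camera adjusted p = 0.000508; adjusted p = 0.361 with an estimated correlation), among them Mest (1.59-fold), Pparg (1.53-fold) and Nnat (at least 1.68-fold). Of 10 sebaceous gland genes 4 fell (median -0.34, camera adjusted p = 0.0241; adjusted p = 0.188 with an estimated correlation), with the wax synthase gene Awat2 2.17-fold and the receptor gene Mc5r 1.80-fold lower. This call ended under 5 of 32 alternatives, among them slide 3 alone (adjusted p = 0.0945), the muscle score as a covariate (adjusted p = 0.0659), no filter on dim probes (median -0.04) and the omission of P15 control replicate 3 (adjusted p = 0.0742). Of 8 inner root sheath genes 3 fell (median -0.24, camera adjusted p = 0.0344; adjusted p = 0.123 with an estimated correlation). This call ended under 14 of 32 alternatives, among them the omission of P15 control 1, 2 or 6 or of P15 mutant 1, 2 or 4 (adjusted p from 0.0516 to 0.0717). Of 15 bulge stem cell genes 3 fell, namely Krt15 (2.28-fold), Nfatc1 (1.44-fold) and Tcf7l1 (1.68-fold), with a list median of -0.23 (camera adjusted p = 0.0437; adjusted p = 0.342 with an estimated correlation). The camera call ended under 17 of 32 alternatives, among them median scaling (median -0.12), the muscle score as a covariate (median -0.09) and the omission of P15 control 1, 3 or 5 or of P15 mutant 1, 2 or 5 (adjusted p from 0.0541 to 0.139). Of 7 mast cell genes 3 rose (median 0.75, camera adjusted p = 0.0124; adjusted p = 0.302 with an estimated correlation), with the histidine decarboxylase gene Hdc 2.13-fold higher. This call ended with the muscle score as a covariate (adjusted p = 0.0854). Of the 21 muscle genes 0 passed (median 0.91, camera adjusted p = 0.00984; adjusted p = 0.685 with an estimated correlation), and their median was -0.14 on slide 3 and 2.16 on slide 4. The muscle call ended without P15 control 1 or 3 or P15 mutant 1 or 2 (adjusted p from 0.0618 to 0.136). Of 28 epidermal differentiation genes 6 rose and 3 fell at P15 (median -0.03, camera adjusted p = 0.992). With members detected in 1 group only set at their bound, the P15 medians were -0.62 for keratin-associated protein, 0.53 for proliferation, 0.56 for melanocyte and 0.49 for mast cell genes. On slides 3 and 4 alone the medians were -0.65 and -0.70 for keratin-associated protein, -0.34 and -0.30 for hair shaft keratin, 0.55 and 0.64 for proliferation, 0.87 and 0.57 for melanocyte, 0.46 and 0.45 for Wnt target, 0.34 and 0.66 for stress response, -0.54 and -0.36 for adipocyte, -0.25 and -0.43 for sebaceous, -0.21 and -0.19 for inner root sheath, -0.10 and -0.22 for bulge and 0.67 and 0.57 for mast cell genes.

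The P15 tests were made as at P10. Alone, slide 3 gave 88 genes and slide 4 gave 462, the P15 arrays fitted without the P10 arrays gave 1017, and without P15 mutant replicate 5 the count was 1816. With arrays scaled on their medians, 63.6% of called genes were higher, against 48.6% here, and the medians were -0.63 for hair shaft keratin and -0.55 for inner root sheath genes.

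**Figure D2:**
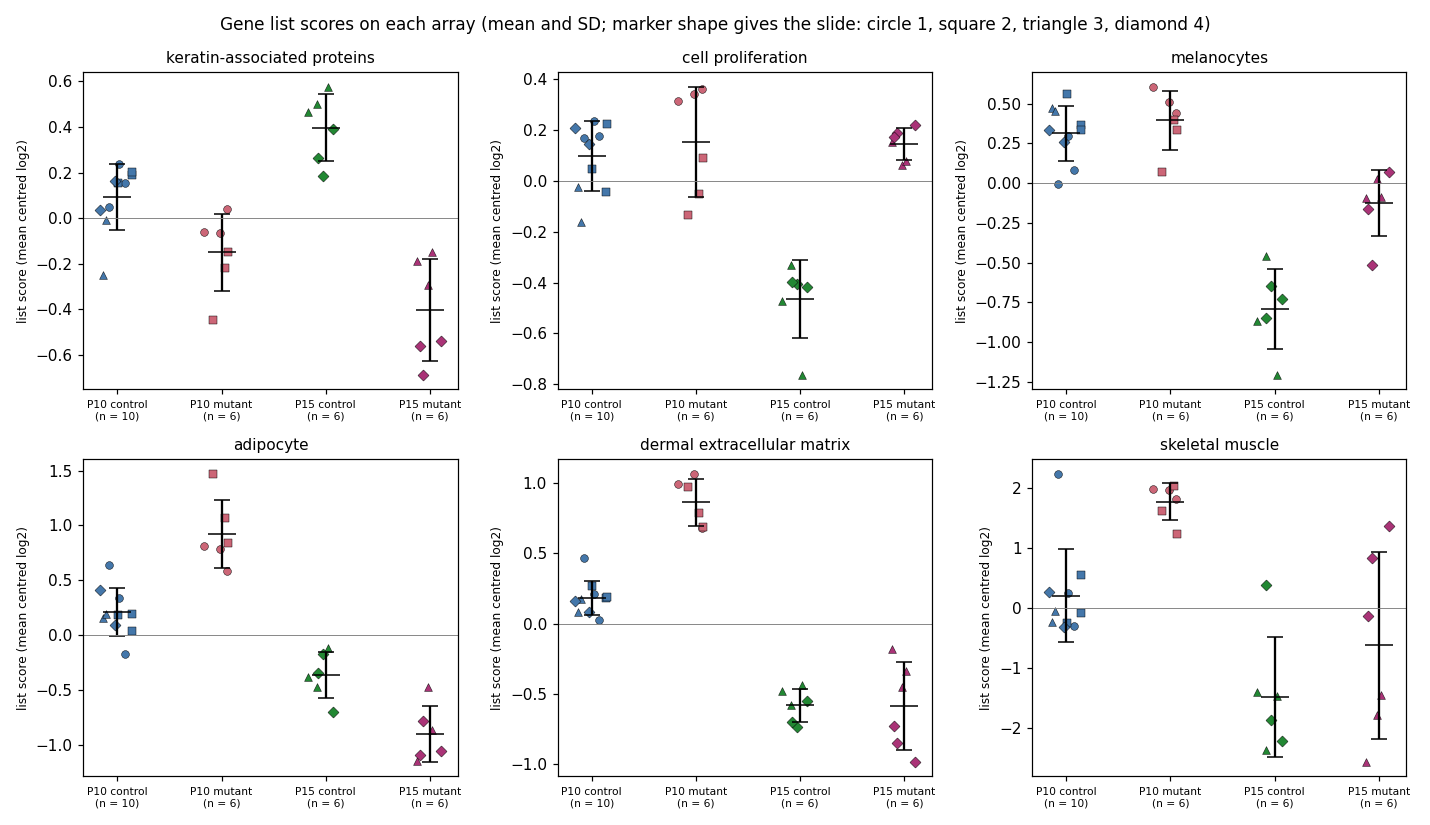
Score of 6 gene lists on each array, the mean over list members of the log2 signal centred on each gene's mean over all arrays, by group, with the horizontal bar for the group mean, the whisker for the SD and marker shape for the slide. Proliferation scores of P15 mutants lay near those of P10 skin, while muscle scores were spread widely within groups, with P10 control replicate 7 at 2.23.

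The mutant effect of one age was then compared with that of the other. Of the genes called at both ages, 214 were higher at both, where independent lists would share 80.9 (Fisher's exact test, two-sided, p = 1.04e-45), and 432 were lower at both, where 84.5 would be shared (p = 4.06e-240). The calls ran in opposite directions for 25 genes, against 165.5 for independent lists. Genes are not independent replicates, and the correlation of the effects across genes was 0.55. Mutants and controls held the same positions on the slides at both ages. An effect of position would therefore also be shared, and it cannot be told apart from genotype here. Shared falls included Upk1b, Fxyd4, Chrna4, the calcium channel gene Trpv6 (log2 difference -1.71 at P10 and -1.43 at P15), Apoe (-1.54 and -1.59) and the immediate early gene Egr1 (-1.60 and -1.35). Shared rises included Wfdc18 (1.84 and 2.24) and the microtubule regulator Stmn1 (1.58 and 1.17). Without P15 mutant replicate 5, 633 genes moved the same way at both ages, against 646 with it.

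**Figure D3:**
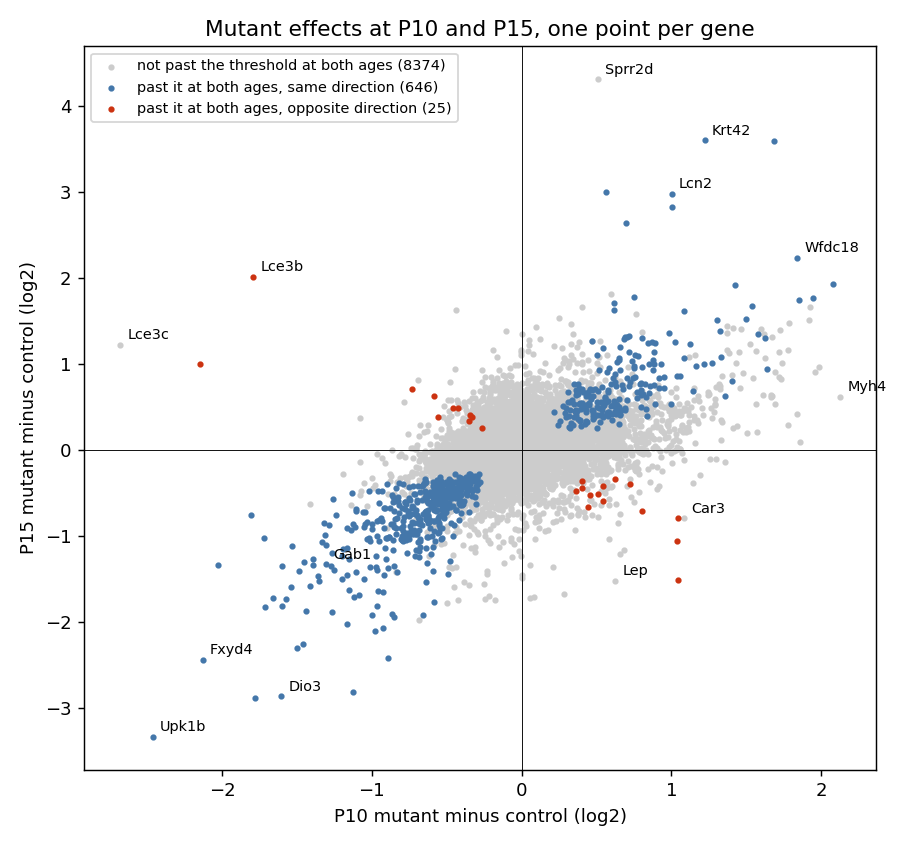
Mutant minus control log2 difference of each of the 9045 genes at P10 (horizontal axis) and at P15 (vertical axis), with genes past the threshold at both ages in blue where they moved the same way (646) and in red where they did not (25). Upk1b and Fxyd4 lie at the lower left, Krt42 and Wfdc18 at the upper right, and Lce3b among the genes of opposite direction.

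A test of the difference between the effects found 341 genes, 170 with a higher and 171 with a lower effect at P15. Lce3b was lower in P10 mutants and higher in P15 mutants (3.80 apart on the log2 scale, SE 0.67, limma adjusted p = 0.00194). Lce3c (3.91, SE 0.69), Sprr2d (SE 0.49), Idi2 (3.15, SE 0.46) and Defb14 (SE 0.28) also had a higher effect at P15. Defb14 and Sprr2d were detected on 0 of 6 P10 controls, and Defb14 on 0 of 6 P15 controls, so the size of their difference is not known. Lce3b, Lce3c, Idi2, Mest and Pacsin1 were undetected on some arrays, so their differences are fitted values that partly rest on background. Nnat, an imprinted gene of fat and other tissues, rose by 1.04 at P10 and was at least 1.68-fold lower at P15 (limma adjusted p of the difference 1.46e-05), where it was detected on 0 of 6 mutants. The effect was also lower at P15 for Mest (difference -2.10, SE 0.39), Pacsin1 (-1.95, SE 0.24) and the muscle and fat carbonic anhydrase gene Car3 (-1.87, SE 0.42). Lep also passed (-2.14, SE 0.57, limma adjusted p = 0.0308), but not without any of P10 controls 6, 9 and 10, P10 mutants 4 and 6 and P15 controls 1, 2 and 5 (adjusted p from 0.0507 to 0.0631). Of 16 adipocyte genes 10 had a lower effect at P15 (median -1.08, camera adjusted p = 1.72e-18; adjusted p = 0.0246 with an estimated correlation), as did 9 of 24 dermal matrix genes (median -0.63, camera adjusted p = 3.41e-11; adjusted p = 0.0503 with an estimated correlation), 7 of 28 keratin-associated protein genes (median -0.32, camera adjusted p = 3.51e-07; adjusted p = 0.123 with an estimated correlation), 3 of 10 hair shaft keratins (median -0.38, camera adjusted p = 0.000106; adjusted p = 0.0163 with an estimated correlation) and 2 of 12 fatty acid synthesis genes (median -0.22, camera adjusted p = 0.0224; adjusted p = 0.148 with an estimated correlation). The fatty acid call ended under 7 of 45 alternatives, among them median scaling (median -0.06, adjusted p = 0.0815) and the omission of P15 control replicate 3 (adjusted p = 0.0532). The effect was higher at P15 for 7 of 21 proliferation genes (median 0.64, camera adjusted p = 6.17e-12; adjusted p = 0.0163 with an estimated correlation), 5 of 19 stress response genes (median 0.45, camera adjusted p = 4.59e-06; adjusted p = 0.123 with an estimated correlation) and 2 of 13 melanocyte genes (median 0.54, camera adjusted p = 0.000146; adjusted p = 0.212 with an estimated correlation). The gene count depended on single arrays: it was 580 without P15 mutant replicate 5, 214 without P10 mutant replicate 1, 220 without P10 control replicate 10 and 221 without P10 control replicate 6. It was 207 with median scaling and 1389 with array weights.

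The last comparison followed control skin from P10 to P15, on slides 3 and 4, which held both ages. By camera, pigment, dermal matrix and proliferation genes fell and keratin-associated protein and stress response genes rose, but these calls ended with an estimated correlation (adjusted p from 0.0503 to 0.278). Hair shaft keratins had no camera call (3 of 10 higher, 1 lower, median 0.09, adjusted p = 0.317). Of the 9045 genes 1976 passed, 1028 higher and 948 lower at P15. The peptide hormone gene Pyy was at least 4.20-fold higher at P15 (limma adjusted p = 2.63e-06), Hamp2 6.44-fold, the secretoglobin gene Scgb1a1 3.73-fold, Tro 3.70-fold and Fam180a 2.37-fold. The perinatal myosin gene Myh8 fell 24.4-fold (SE 0.74, limma adjusted p = 2.49e-05), and at P15 it was detected on 1 of 6 arrays. Dlk1, an imprinted gene of immature cells, was at least 3.44-fold lower, Sln 3.62-fold, Ddx6 6.16-fold and Zbtb7a 6.06-fold. Of 13 melanocyte genes 10 fell (median -1.34, camera adjusted p = 2.56e-10; adjusted p = 0.0503 with an estimated correlation), with the melanocortin receptor gene Mc1r at least 1.82-fold and the tyrosinase gene Tyr at least 1.57-fold lower. Of 24 dermal matrix genes 15 fell and 1 rose (median -0.80, adjusted p = 0.0569 with an estimated correlation), with Dcn 1.96-fold and Col6a2 2.02-fold lower, and of 21 proliferation genes 12 fell (median -0.49, adjusted p = 0.0512 with an estimated correlation), with Mcm7 at least 1.53-fold and Birc5 1.68-fold lower. Of 28 keratin-associated protein genes 13 rose and 3 fell (median 0.44, adjusted p = 0.201 with an estimated correlation), among them Krtap1-4 (2.59-fold), and of 19 stress response genes 11 rose and 2 fell (median 0.55, adjusted p = 0.278 with an estimated correlation), with Krt16 2.15-fold higher and Stfa1 4.45-fold lower.

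Further lists moved with age in controls, each with a camera call that was lost with an estimated correlation. Of 16 adipocyte genes 8 fell (median -0.51, adjusted p = 0.361 with an estimated correlation), of 21 muscle genes 7 fell (median -1.29, adjusted p = 0.493 with an estimated correlation), of 7 mast cell genes 4 fell (median -0.85, adjusted p = 0.270 with an estimated correlation) and of 14 dermal papilla genes 6 fell and 1 rose (median -0.26, adjusted p = 0.123 with an estimated correlation), with Fgf7 1.25-fold and Fgf10 1.84-fold lower. The dermal papilla call ended under 24 of 35 alternatives, among them the omission of P10 control 1, 2, 4, 5, 6 or 8 or of P15 control 3, 4 or 5 (adjusted p from 0.0502 to 0.0960). The mast cell call ended with the muscle score as a covariate (adjusted p = 0.128). Of 13 Wnt targets 2 fell, Sp5 (at least 1.25-fold) and Wif1 (1.65-fold), with a list median of -0.19 (adjusted p = 0.212 with an estimated correlation). That call ended under 16 of 35 alternatives, among them the omission of P10 control 1 or 2 or of P15 control 3 or 4 (adjusted p from 0.0571 to 0.122). Of 28 epidermal differentiation genes 10 rose and 1 fell (median 0.31, adjusted p = 0.459 with an estimated correlation), of 10 barrier lipid genes 3 rose (median 0.28, adjusted p = 0.302 with an estimated correlation), and of 11 immediate early genes 4 rose (median 0.36, adjusted p = 0.150 with an estimated correlation), among them Junb (1.57-fold) and Zfp36 (1.53-fold). Without P15 control replicate 3 the epidermal differentiation and barrier lipid calls ended (adjusted p = 0.0742 and 0.0568). They ended under 6 and 11 of 35 alternatives, the barrier lipid call also with median scaling (median 0.04, adjusted p = 0.110), on slide 3 alone (adjusted p = 0.298) and without P10 control 1 or 2 (adjusted p = 0.122 and 0.0691). On slides 3 and 4 alone the medians were 0.58 and 0.27 for keratin-associated protein, -1.47 and -0.96 for melanocyte, -0.74 and -0.80 for dermal matrix, -0.40 and -0.58 for proliferation and 0.59 and 0.67 for stress response genes. On slide 4 alone the keratin-associated protein and epidermal differentiation calls ended (adjusted p = 0.0594 and 0.0610). Slide 3 alone gave 1049 genes and slide 4 alone 283, and the fit without a slide term gave 3642. With arrays scaled on their medians the median of all genes lay at -0.23 and 9.18% of called genes were higher, against 52.0% here, so directions of single genes are relative to the quantile scaling. Median scaling moved the list medians to 0.26 for keratin-associated protein, 0.34 for stress response, 0.13 for epidermal differentiation, 0.15 for immediate early, -0.83 for proliferation, -0.50 for Wnt target and -0.43 for dermal papilla genes. With members detected at 1 age only set at their bound, the medians were -1.25 for melanocyte, -0.47 for adipocyte and -0.06 for dermal papilla genes.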

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

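The tests of a younger profile at P15 and at P10 were chosen only after the list results had been seen, and the muscle and brightness covariates and the omission of single controls from the muscle test were added after the gene counts and lists had been seen. A sample was singled out where its gap to the nearest of its group exceeded the 95% critical value of Dixon's test for a group of that size, in 136 such checks of array measures, named genes and list scores. This picks about 1 group in 20 by chance, and it picked 13. P15 mutant replicate 5 stood apart, with a median raw signal of 172 against 53.2 to 65.9 on the other P15 mutants and 8836 detected probes against 10638 to 11132. P10 mutant replicate 6 had a median raw signal of 105 against 126 to 133. P10 control replicate 7 stood above the other P10 controls in muscle genes, with log2 signals of 8.84 for Myh4, 8.59 for Ppp1r27, 11.28 for Ckm, 8.66 for Csrp3 and 11.28 for Cox6a2 and a muscle list score of 2.23. P10 mutant replicate 5 was low in Ckm at 9.87 against 10.73 to 11.15. P15 control replicate 2 had a muscle list score of 0.39 against -2.36 to -1.40. P10 control replicate 3 was low in the keratin-associated protein score at -0.25, and P15 control replicate 5 in the proliferation score at -0.76.

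Effects that differed between the ages by the test of the difference numbered 341. The named genes were Lce3c (3.91), Lce3b (3.80), Sprr2d (3.80), Idi2 (3.15), Defb14 (2.44), Nnat (-2.55), Lep (-2.14), Mest (-2.10), Pacsin1 (-1.95) and Car3 (-1.87), as fitted log2 differences of the P15 and P10 effects. Those of Nnat, Defb14 and Sprr2d rest on groups in which the probe was detected on 0 arrays, so their size is not known. List medians of that difference were -0.38 for hair shaft keratins, -0.32 for keratin-associated proteins, 0.45 for stress response, -1.08 for adipocyte, -0.22 for fatty acid synthesis, 0.64 for cell proliferation, -0.63 for dermal matrix and 0.54 for melanocyte genes. With an estimated correlation the calls ended for keratin-associated proteins and stress response (adjusted p = 0.123 each), fatty acid synthesis (0.148), dermal matrix (0.0503) and melanocyte genes (0.212). Among the 732 tested probes without a symbol, which no gene test used, 109 passed at P10 and 162 at P15.

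For chance, 100 splits of the same arrays within slides were counted, the real split among them. No other split gave as many genes as the real one at P10 (1 of 100, 1687 genes against at most 1398), at P15 (1 of 100, 1774 against 658) and for age in controls (1 of 100, 1976 against 242). A share of 1 of 100 is the smallest that these splits can give. Chance is therefore unlikely for these counts but not excluded. For the difference, 5 of 100 splits, the real one included, gave at least its 341 genes, up to 810, so chance was not excluded by this count. In the splits with 810 and 653 genes, 1 of 6 P10 mutants and 5 of 6 P15 mutants kept their group, which turns an effect shared by both ages into a difference, so these counts point to a structure of the samples. The splits with 729 and 434 genes kept 2 and 3 P10 mutants and 0 and 6 P15 mutants. The shared effect enters such splits, so they do not measure chance alone for the difference, and it stays open.

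Skeletal muscle genes were among the largest rises at P10. Unequal amounts of muscle in the pieces of skin may account for this, but the test left it open. Among P10 controls the muscle list score varied within slides with an SD of 0.83, which is 0.604 of the mutant-control difference of 1.37. This rests on P10 control replicate 7, without which the SD was 0.37, or 0.217 of a difference of 1.73. Abundant muscle transcripts moved together, with Ckm at 8.76 in controls and 10.72 in mutants and Tnnt3 at 9.45 and 11.37. A change of muscle with genotype stays open as untested, since 6 of 6 P10 mutants exceeded the 9 P10 controls other than replicate 7 in Ckm.

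Dermal matrix and adipocyte genes also rose at P10, although both list calls ended with an estimated correlation. With the muscle score as a covariate the difference of the dermal matrix score was 0.70 (95% interval 0.48 to 0.92), against 0.64 without it, and that of the adipocyte score 0.58 (0.23 to 0.92) against 0.72. The median raw signal was above that of the P10 controls on 5 of 6 P10 mutant arrays, but with array brightness as a covariate the differences were 0.57 (0.38 to 0.76) and 0.80 (0.47 to 1.12). The values with the muscle score argue against muscle content as the whole cause only if its slope is the same in all groups. The muscle score spread most in P15 mutants (SD 1.55) and P15 controls (0.99). In P10 controls the SD was 0.77 and in P10 mutants 0.31, so the slope rests largely on P15 arrays. The brightness test cannot decide, since P15 mutant replicate 5 dominated the spread of brightness within groups. Its median raw signal was 172, against 56.0 and 53.2 on the other P15 mutants of its slide. How deep each piece of skin was cut was not measured, and a genotype effect on dermis and fat remains a hypothesis beside it.

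P15 mutant effects ran against the age change of controls. The correlation across the 9045 genes was -0.40, but both use the P15 controls, and simulated unchanged groups gave -0.45. The covariance was -0.072 against -0.016 simulated. With the age change from one slide and the mutant effect from the other, so that no array was shared, the correlations were -0.31 and -0.23, which argues against shared arrays as the whole cause. Without P15 mutant replicate 5 their mean was -0.25. That array lies on slide 3, so the -0.31, from mutants on slide 4, never used it. The other correlation moved from -0.23 to -0.18 without it, which argues against that array as the whole cause. On both slides P15 mutants lay at positions A to C, P15 controls at D to F and P10 controls at G and H. An effect of position could therefore also give negative correlations between slides, and exchanging the slides cannot remove it.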

How the results depend on the processing

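The settings with muscle content or array brightness as a covariate were chosen after the data were seen, and the others were planned. Of 194 counts of genes under an alternative, 168 stayed within 1.5 times the reported value, as did the 5 counts with the authors' processed values. Leaving out a single array gave 95 of the 168 and only 5 of the counts that moved further, so most of those moved under the other alternatives. Counts in the order P10, P15, difference and age are given where they moved further, and except where a construction is named the cause was not tested. Requiring at least 1.5-fold gave 797, 858 and 1089 genes at P10, P15 and with age, by construction. Median scaling gave 207 for the difference. Without the slide term the difference gave 207 and age 3642. The 2 groups alone gave 1017 at P15. Array weights gave 4301 at P10 and 1389 for the difference. Array brightness as a covariate gave 614 for the difference. Slide 1 alone gave 3753 and slide 2 alone 848 at P10, slide 3 alone 88 and slide 4 alone 462 at P15, and 1049 and 283 with age. At an unadjusted p below 0.05, by construction, 1238 genes moved the same way at both ages instead of 646.

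The replicate numbers were not taken to pair the samples, so the replicate block is given only here. It gave 5 genes at P10, 0 for the difference (at which limma with the slide term alone gave 341, and 1589 at an unadjusted p below 0.05), 1104 with age and an overlap of 3, and 1661 at P15. No P10 mutant shares its number with a P10 control on its own slide, so the block leaves little to compare at P10. Under it the P10 values turned for the keratin-associated protein list (0.17), the mast cell list (-0.022), Csrp3 (-0.42), Tpsab1 (-0.90) and Hdc (-0.022). The muscle list at P15 turned on slide 3 alone (-0.14).

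Leaving out each array in turn gave 1049 to 1942 genes at P10, 1448 to 1821 at P15, 214 to 580 for the difference, 1496 to 2046 with age and 494 to 660 in the overlap. The lowest P10 count came without P10 control replicate 6, and the difference gave 580 without P15 mutant replicate 5, 214 without P10 mutant replicate 1, 221 without P10 control replicate 6 and 220 without P10 control replicate 10. Of list values under alternatives 1319 kept their call, 162 lost it and 3 turned, with 35 of the losses from the estimated correlation. Of named gene values 6840 kept their side of the threshold, 390 lost it, 66 gained it and 3 turned. Leaving out a single array gave 662 of the kept and 42 of the lost list values. For named genes it gave 3413 of the kept, 100 of the lost and 27 of the gained values. The muscle list and its members were not judged with the muscle covariate, which is made from them, so a median near 0 there is by construction. Signals near background limit folds of genes detected on some arrays only.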

Other observations

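The lists of signalling genes below had no camera call at P10 or P15, so only single members are described. Of 11 ERK response genes 3 fell and 0 rose at P10 and 3 fell and 1 rose at P15: Dusp6, a phosphatase induced by ERK, fell 1.73-fold at P10 (SE 0.12 on the log2 scale, limma adjusted p = 4.39e-05) and 1.84-fold at P15 (SE 0.12, limma adjusted p = 5.97e-06), Phlda1 fell 1.66-fold and 1.60-fold, Dusp4 fell 1.37-fold and 1.60-fold, and Ccnd1 rose 1.34-fold at P15. The list's camera adjusted p was 0.112 at P10 and 0.530 at P15. Among 15 receptor tyrosine kinase pathway genes, with Gab1 itself among those that fell at both ages, 3 rose and 3 fell at P10 and 2 rose and 5 fell at P15 (camera adjusted p = 0.588 and 0.317), with the ligand genes Hbegf 1.65-fold lower at P10, Epgn 1.98-fold higher and Btc 2.12-fold lower at P15. Among 22 hair cycle regulators 4 rose and 4 fell at P10 and 2 rose and 5 fell at P15 (camera adjusted p = 0.762 and 0.279). Fgf5, a growth factor known to end the growth phase of the follicle, fell 2.90-fold at P10 (SE 0.16) and 2.17-fold at P15 (SE 0.16), Fgf22 fell 1.55-fold and 2.48-fold, and Esr1 rose 1.98-fold at P10.

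Other cell types and pathways gave mixed values. The T cell genes Cd3e and Cd3g fell 2.02-fold and 1.78-fold at P15 too, while the complement gene C1qa rose at least 1.63-fold there, and the immune cell list as a whole had 7 higher and 3 lower of 19 (camera adjusted p = 0.305). Of 14 dermal papilla genes 3 rose and 2 fell at P15 (camera adjusted p = 0.549), with Wif1 1.84-fold higher and Crabp1 1.43-fold lower. The myelin gene Mbp (1.82-fold) and the neurotrophin receptor gene Ngfr (1.54-fold) were among the 3 genes that fell at P15 of 8 Schwann cell genes (camera adjusted p = 0.207). Of 14 cholesterol synthesis genes 4 fell at P10 and 4 fell and 1 rose at P15 (camera adjusted p = 0.0889 and 0.690), with Insig1 1.61-fold and 2.25-fold lower. No camera call was made in any of the 4 contrasts for hair matrix regulators (adjusted p = 0.463 at P10 and 0.391 at P15), hedgehog (0.862 and 0.588), BMP and TGF-beta (0.366 and 0.917), p53 and apoptosis (0.992 and 0.947), red blood cell (0.588 and 0.225), endothelium (0.742 and 0.833), interferon (0.971 and 0.762), circadian clock (0.530 and 0.992) and sex-linked genes (0.988 and 0.782).

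The hypothesis that mutant skin keeps a younger profile at P15 was tested on genes called in the age change on one slide and mutant effects on the other, a test fixed after the lists were seen. Of 574 genes that rose with age on slide 3, 387 (67.4%) were lower in mutants on slide 4, and of 475 that fell, 335 (70.5%) were higher. With the slides exchanged the shares were 73 of 98 (74.5%) and 117 of 185 (63.2%). The lowest share, 63.2%, was above the limit the hypothesis had been given, so the values are in line with it. Stress response genes, higher in P15 mutants (median 0.40) and with age (median 0.55), and adipocyte genes, lower in P15 mutants (median -0.43) and with age (median -0.51), go against it. The calls of both lists ended in both comparisons with an estimated correlation, so these shifts are uncertain. P10 mutant effects also ran against the age change, with a correlation of -0.25 across genes, so this is not particular to P15. The controls in the P10 effect and the P15 controls lay at the same positions, D to F. An effect of position could therefore also give this value. For P10 mutants, whose arrays the age change does not use, 64.7% of 1028 genes that rose with age were lower and 57.7% of 948 that fell were higher. That last share lay between the limits for and against, so the hypothesis of a younger profile at P10 was left undecided. This P10 test was written after list values at that age were known.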
